A study of Mus musculus with 248 samples.

How the data were processed

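Single HSCs of C57Bl6 mice were sorted by MMP, inspected on a Fluidigm C1 chip so that debris, doublets and dead cells were left out, and made into cDNA with the SMART-Seq v4 kit and into libraries with Nextera XT, per the labels' protocols. This chemistry copies full-length polyadenylated RNA and carries no molecular identifiers, so reads of 1 library are not independent molecules. The labels state 254 libraries on 3 lanes with single reads of 100 nt, of which 122 MMP-low and 126 MMP-high libraries were described. The submitters' processing notes name bcl2fastq 2.17.1.14, STAR 2.5.2b and the genome build mm10. Alignment settings, the annotation and the program behind the quality values are not given in the sources used here.

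Counts of total and mapped reads and numbers of detected genes per library are the authors' own, per the file headers, and the threshold for calling a gene detected is not stated. Alignment, intron and intergenic values were deposited as fractions of reads per library and were turned into percent. The authors' deposited gene tables give a p-value and an adjusted p-value per gene, and the adjusted value equals the p-value times 16203, taken here as the number of genes tested. The title of the MMP table names MAST, a model for single-cell expression, per the file headers. Its fold changes are average log values in a base the authors do not state, and detection is the fraction of cells per group, turned into percent. Every gene listed by the authors had a log fold change of at least 0.25 and a p-value of at most 0.00999, and 492 of the 1868 listed genes had an adjusted p of 1. The authors' deposited enrichment tables give an overlap, an adjusted p-value and a combined score per term, without naming the tool or the background. The deposited pathway table gives z scores of pairs of clusters. The authors' normalization, filling in of values or batch correction, if any, is not given in the sources used here, and each would move folds and detection.

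The titles put each library in its group and give it a number. No animal, donor or sort is named, so each group was 1 sample, cells were not used as replicates, and no new p-value, standard error or count of changed genes was made from cells. The authors' p-values for the MMP groups come from a model of single cells. With no animal named, they are not read here as measuring a spread between animals. Counts of genes by adjusted p use them as given. Quality values were described by median, mean, range and SD over cells. Shares of libraries have exact Clopper-Pearson intervals at a confidence level of 95%, and a share of 0 is given with the share that 3 counts would make. Intervals and limits cover counting error only. As a technical split, libraries numbered up to 85 were compared apart from those above, since about that number shared a lane per the labels; whether the number follows a lane or chip is not stated. Which libraries shared a lane is not stated either, so that lane and group can be confounded within the libraries numbered up to 85. Exonic reads were taken as mapped reads times the expression profiling efficiency, which exceeded the alignment rate in 99 of 248 libraries and so was read as a share of mapped reads.

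The named genes were fixed before the data were examined. For the MMP table they were the 10 genes of largest fold in each direction, without predicted genes (Gm numbers, Rik names and -ps pseudogenes), and up to 4 listed members of each fixed list by fold. For every other gene table they were the 5 leading genes by fold per cluster or list and up to 4 members of each fixed list, ties by symbol order, and part of these are named in the text. Predicted genes were left out of these 5 leading genes too, which the rule for these tables had not stated. Any other named gene is said to have been chosen after its values were seen. The 26 fixed lists were also set in advance. They cover lysosomal hydrolases and membrane proteins, vacuolar ATPase subunits, autophagy, the respiratory chain and ATP synthase, mitochondrially encoded genes, the tricarboxylic acid cycle, the mitochondrial ribosome with import and dynamics, glycolysis, ribosomal proteins, ribosome biogenesis and translation, the proteasome, G1/S, G2/M, stem cell and quiescence genes, FOXO and antioxidant genes, mTOR and nutrient sensing, immediate early genes, cholesterol and fatty acid metabolism and the interferon response. The other lists hold markers of megakaryocytes, erythroid cells, granulocytes with monocytes and macrophages, lymphoid cells, multipotent progenitors, mast cells with eosinophils and basophils, and endothelial and stromal cells. The result of the megakaryocyte list is not reported here.

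For each list with at least 5 listed genes, the median signed fold (positive toward MMP-low) was ranked among 10000 random lists of the same size from the same table (seed 20). Matching on mean expression was not possible, as the table gives none. On simulated lists of 15 genes drawn from the 1868 genes, the median put 76% of lists whose members all pointed one way outside the central 95% and 5% of random lists. The mean and the share of members pointing one way, the latter added after this was seen, put 100% of the former outside. A list that points one way can thus be missed by the median, which was kept as the measure fixed in advance. Overlaps were counted by symbol and set beside n1 x n2 / N. Alternatives covered thresholds on adjusted p and fold, kinds of genes, the list measure, the split of libraries and the filter. Gene positions come from the GENCODE vM21 annotation of the mm10 assembly, matched by symbol, and 11 of the 1868 symbols, Erdr1 among them, had no match. Values were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.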

Results

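Hematopoietic stem cells (HSCs) keep blood formation going for life, and the series asked how such cells of low and high mitochondrial membrane potential (MMP) differ when each cell is sequenced on its own. The potential is the voltage across the inner mitochondrial membrane. Cells were sorted from C57Bl6 mice as lineage-negative, Sca1 and cKit positive, CD150 positive and CD48 negative, a surface profile of long-term HSCs, and then by potential. Each library held the RNA of 1 cell captured on a microfluidic chip. There were 122 MMP-low and 126 MMP-high libraries. The labels name no animal or sort behind a cell, so each group counted as 1 sample, and differences between the groups have no replicate check. The files analysed here held quality values per library and the authors' result tables, not expression values per cell.

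MMP-high libraries held more detected genes than MMP-low libraries, with a median of 3796 against 2317. The ranges were 1130 to 5200 genes in MMP-high and 514 to 3674 in MMP-low, and the SD over cells was 1112 and 681. Median total reads were 1816108 in MMP-high and 1620811 in MMP-low, with ranges of 949570 to 4308287 and 678723 to 5074155. Median mapped reads were 568088 and 508338 over all libraries. Reads in introns were more frequent in MMP-low, with a median of 42.7% against 34.2%, as were reads between genes, at 37.7% against 31.7%.

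The difference in genes detected depended on the set of libraries. The titles number the cells within each group, and libraries numbered up to 85 were compared apart from those above. Up to 85, the medians were 4080 genes in 85 MMP-high libraries and 2500 genes in 85 MMP-low libraries. Above 85, they were 1905 genes in 41 MMP-high libraries and 2083 genes in 37 MMP-low libraries, so that the order of the groups turned. Mapped reads turned as well, with medians of 1035705 in MMP-high and 472174 in MMP-low up to 85 and of 454512 and 564476 above. Up to 85, reads between genes made up 20.7% in MMP-high and 35.5% in MMP-low, and above 85 they made up 40.3% and 38.7%. The intron share was 21.1% and 37.5% up to 85, and 45.5% and 46.1% above. The expression profiling efficiency was 58.5% in MMP-high and 24.5% in MMP-low up to 85, and 13.7% and 14.6% above. Among libraries with 300000 to 600000 mapped reads, a window chosen after the data had been seen, the medians were 4545 in MMP-high and 2502 in MMP-low up to 85, and 1904.5 and 2053.5 above.

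**Figure D1:**
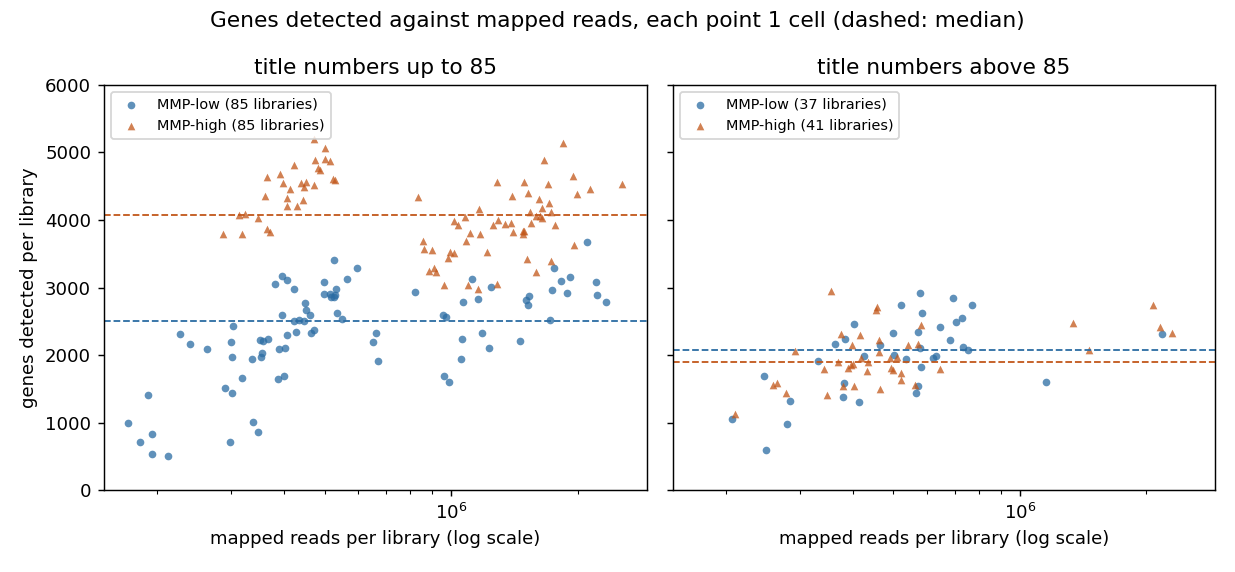
Genes detected per library (vertical axis, number) against mapped reads (horizontal axis, log scale), each point 1 cell, for title numbers up to 85 (left) and above 85 (right); dashed lines are medians. MMP-high libraries lie above MMP-low libraries on the left, with medians of 4080 and 2500, and among them on the right, with medians of 1905 and 2083.

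No library in the quality table met the filter stated for the series, which asks for more than 600000 reads and more than 5500 genes. All 122 MMP-low and all 126 MMP-high libraries passed the read minimum. The gene minimum was met by 0 of 122 MMP-low libraries, which allows a share of up to 2.46%, and by 0 of 126 MMP-high libraries, which allows up to 2.38%. At a minimum of 5000 genes, 3 of 126 MMP-high libraries passed (2.38%, exact Clopper-Pearson 95% interval 0.494% to 6.80%). These limits and intervals cover counting error only. The 224 cells that the series states as kept could therefore not be told from the quality table, and which libraries entered the authors' result tables is not given in the sources used here.

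Genes of granulocytes led the side of MMP-low cells, while genes of DNA replication and cell division were among the leaders on that of MMP-high cells. The authors' deposited table of this comparison listed 949 genes as higher in MMP-low and 919 as higher in MMP-high, with log fold changes of at least 0.25 in a log base that the file does not state. S100a9 and S100a8, calcium-binding proteins abundant in neutrophils, had log fold changes of 2.15 and 2.05 in favour of MMP-low in the authors' deposited table. Trim28, a corepressor of transcription, and Stmn1, a regulator of microtubules in dividing cells, led the other direction in the authors' deposited table, at 0.93 and 0.80 in favour of MMP-high. With an adjusted p under 0.05, the authors' deposited table left 539 genes higher in MMP-low and 598 higher in MMP-high, so the longer list changed sides. Without members of the fixed cell type marker lists the numbers from the authors' deposited table were 927 and 916, and without genes detected in at most 1% of the other group they were 896 and 914.

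Among the 10 genes with the largest fold on the MMP-low side, predicted genes left out, were further granule and antimicrobial proteins. With all genes kept, the predicted genes Gm10800, Gm21738 and Gm26870 ranked 3, 8 and 9 on this side, at 1.88, 1.63 and 1.53. They were chosen after their values were seen. In the authors' deposited table the log fold change was 1.86 for Ltf (lactoferrin), 1.83 for Camp (cathelicidin) and 1.81 for Ngp, and these genes were detected in 100% of MMP-low cells and in 30.3%, 46.2% and 31.9% of MMP-high cells. Lyz2 (lysozyme), Chil3, Mgst1 and Lcn2 followed in the authors' deposited table at 1.69, 1.49, 1.38 and 1.34. Ighm, the constant region of the immunoglobulin mu heavy chain, had a log fold change of 1.31 in the authors' deposited table and was detected in 70.5% of MMP-low and 0% of MMP-high cells. In the mm10 assembly, S100a9 lies on chromosome 3 from 90692632 to 90695721, S100a8 on the same chromosome from 90668978 to 90670035, Ltf on chromosome 9 from 111019271 to 111042767, and Ighm on chromosome 12 from 113418558 to 113422730.

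On the MMP-high side, the third to the tenth gene were Erdr1, Ptcd3, Pbk, Mcm6, Hist1h2ap, Hist1h2ao, Adssl1 and Stt3a, with log fold changes from 0.77 down to 0.69 in the authors' deposited table. Ptcd3, a protein of the mitochondrial ribosome, was detected in 78.2% of MMP-high and 23.8% of MMP-low cells per the authors' deposited table. Pbk is a mitotic kinase and Mcm6 a subunit of the replicative helicase. Hist1h2ap and Hist1h2ao are near-identical histone genes, and reads may be split between such copies, so their values of 0.72 each in the authors' deposited table are uncertain. Trim28 lies on chromosome 7 from 12999114 to 13031035, Stmn1 on chromosome 4 from 134468320 to 134473843 and Mcm6 on chromosome 1 from 128331590 to 128359664 in the mm10 assembly.

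Among listed genes, those of stem cells and lysosomes stood mostly on the MMP-low side. Of 49 members of the stem cell and quiescence list, the authors' deposited table gave 21 as higher in MMP-low and 1 as higher in MMP-high. Among them were Nr4a1, a nuclear receptor, with a log fold change of 1.06, Ifitm1 with 0.98, Ly6a, which encodes the sorting marker Sca1, with 0.83, and Mllt3 with 0.82 in the authors' deposited table. Nr4a1 is also a member of the immediate early and handling stress list. Of 48 lysosomal hydrolases and membrane proteins, 9 were higher in MMP-low and 3 in MMP-high in the authors' deposited table, led by Psap (0.79) and the cathepsins Ctsh (0.70), Ctsa (0.62) and Ctsz (0.59). Granulocyte genes led the same side, and whether the lysosomal result is separate from them was not tested. All 5 listed subunits of the vacuolar ATPase, the pump that acidifies lysosomes, were higher in MMP-low in the authors' deposited table, Atp6v1c1 by 0.87 and Atp6ap2 by 0.54. Autophagy genes went both ways, 5 toward MMP-low and 3 toward MMP-high in the authors' deposited table, with Optn at 0.38 and Wipi2 at 0.35 in opposite directions. With an adjusted p under 0.05 the numbers toward MMP-low and MMP-high in the authors' deposited table were 17 and 0 for stem cell genes, 8 and 3 for lysosomal genes, 3 and 0 for the vacuolar ATPase, and 2 and 2 for autophagy, where Wipi2 had an adjusted p of 0.13.

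Of 30 immediate early and handling stress genes, 11 were listed as higher in MMP-low and 4 as higher in MMP-high in the authors' deposited table, with Junb at 0.86 and Egr1 at 0.74. Egr1 and Nr4a1, the member with the largest fold, are in the stem cell and quiescence list too. Of the interferon response list, 4 genes were higher in MMP-low and 1 in MMP-high in the authors' deposited table, where Irf1 had 0.74 and Ifi27 had 0.42 in the other direction with an adjusted p of 0.35. With an adjusted p under 0.05, the authors' deposited table kept 6 and 2 immediate early genes and 2 and 0 interferon genes. Markers of mature cells moved with these groups. Of 27 genes of granulocytes, monocytes or macrophages, the authors' deposited table gave 10 as higher in MMP-low and 2 as higher in MMP-high, of which 10 and 0 had an adjusted p under 0.05. Of 24 genes of B, T and lymphoid progenitor cells, 5 were higher in MMP-low and 1, Nkg7, in MMP-high in the authors' deposited table, of which 4 and 1 had an adjusted p under 0.05. The authors' deposited table also placed on the MMP-low side 3 erythroid genes (Car1, Blvrb and, with an adjusted p of 0.72, Hbb-bt), 2 multipotent progenitor genes (Cd52 and Cd53) and 1 endothelial or stromal gene (Vwf, also a member of another fixed list), and it listed 0 markers of mast cells, eosinophils or basophils.

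Listed cell cycle genes stood mostly on the MMP-high side. All 21 listed members of the G1/S and DNA replication list were higher in MMP-high in the authors' deposited table, with Mcm6 at 0.72, Usp1 at 0.61, the helicase subunit Mcm5 at 0.60 and the thymidylate synthase Tyms at 0.58. Of the G2/M list, 18 were higher in MMP-high and 1 in MMP-low in the authors' deposited table, and the mitotic kinase Cdk1 was detected in 92.4% of MMP-high against 45.7% of MMP-low cells. Listed ribosomal genes mostly followed the same side. The authors' deposited table gave 29 cytosolic ribosomal proteins as higher in MMP-high and 1 as higher in MMP-low, with Rpsa at 0.44 and Rpl34 at 0.41. For ribosome biogenesis and translation the numbers in the authors' deposited table were 15 and 1, with the transcription factor Myc at 0.44, and for the proteasome 11 and 1, with Psmd1 at 0.43. With an adjusted p under 0.05, the authors' deposited table kept 13 G1/S, 9 G2/M, 29 ribosomal, 10 ribosome biogenesis and 3 proteasome genes on the MMP-high side, and 1 ribosome biogenesis gene, Nop2, on the MMP-low side.

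Listed genes of the respiratory chain and ATP synthase were all on the MMP-high side, 15 against 0, of which 10 had an adjusted p under 0.05 in the authors' deposited table. Ndufv1, a core subunit of complex I, had a log fold change of 0.64 and was detected in 89.9% of MMP-high and 29.5% of MMP-low cells in the authors' deposited table. Higher detection of single genes in MMP-high cells stands beside the larger number of genes detected per MMP-high library (4080 against 2500 up to 85) and its higher expression profiling efficiency (58.5% against 24.5%), and the tables do not separate these. Ndufa4, Sdhd and Atp5o followed at 0.57, 0.45 and 0.44 in the authors' deposited table, where Sdhd had an adjusted p of 0.58. Of the tricarboxylic acid cycle and pyruvate dehydrogenase list, 7 were listed toward MMP-high and 1 toward MMP-low in the authors' deposited table, but only 2 of these, Pdhb (0.47) and Ogdh (0.43), had an adjusted p under 0.05, and Idh2 had a log fold change of 0.50 with an adjusted p of 0.052. All 9 listed genes of the mitochondrial ribosome, import and dynamics were on the MMP-high side in the authors' deposited table, 4 of them with an adjusted p under 0.05, with Timm23 at 0.48. Among mitochondrially encoded genes only mt-Nd2 and mt-Nd1 were listed, at 0.41 and 0.26 in favour of MMP-high and each with an adjusted p of 1 in the authors' deposited table. Glycolysis genes were listed 2 against 2 in the authors' deposited table and 0 of them had an adjusted p under 0.05; Ldhb had 0.18 and Pgk1 had 0.055. The numbers toward MMP-low and MMP-high in the authors' deposited table were 3 and 3 for FOXO and antioxidant genes, 2 and 3 for mTOR and nutrient sensing, and 3 and 4 for cholesterol and fatty acid metabolism, where squalene epoxidase, Sqle, was detected in 92.4% of MMP-high and 21% of MMP-low cells. With an adjusted p under 0.05 these numbers in the authors' deposited table were 2 and 1, 0 and 2, and 0 and 3.

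The median log fold change of each list with at least 5 listed genes was set among 10000 random lists of the same size from the authors' deposited table, as a description and not a test. Of 19 such lists, 12 lay outside the central 95% of random lists, 6 on each side. On the MMP-low side these were the lysosomal (percentile 100), vacuolar ATPase (98.6), stem cell and quiescence (100), immediate early (99.6), interferon (99.3) and granulocyte (100) lists. By the share of members higher in MMP-low, the lysosomal (94.9) and immediate early (96.1) lists lay inside the central range, as did the interferon list by mean (93.9) and by share (88.8). The MMP-high side held G1/S (0.010), G2/M (0.020), ribosome biogenesis (0.10), the tricarboxylic acid cycle (0.21), ribosomal proteins (1.69, or 5.84 among genes with an adjusted p under 0.01, inside the central range) and the mitochondrial ribosome (2.25). The respiratory chain list lay at 5.78 although all its listed members pointed to MMP-high, the proteasome at 14.4, lymphoid genes at 96.4 and autophagy at 76.6. Cholesterol and fatty acid metabolism, mTOR and FOXO genes lay at 25.8, 38.1 and 47.6.

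**Figure D2:**
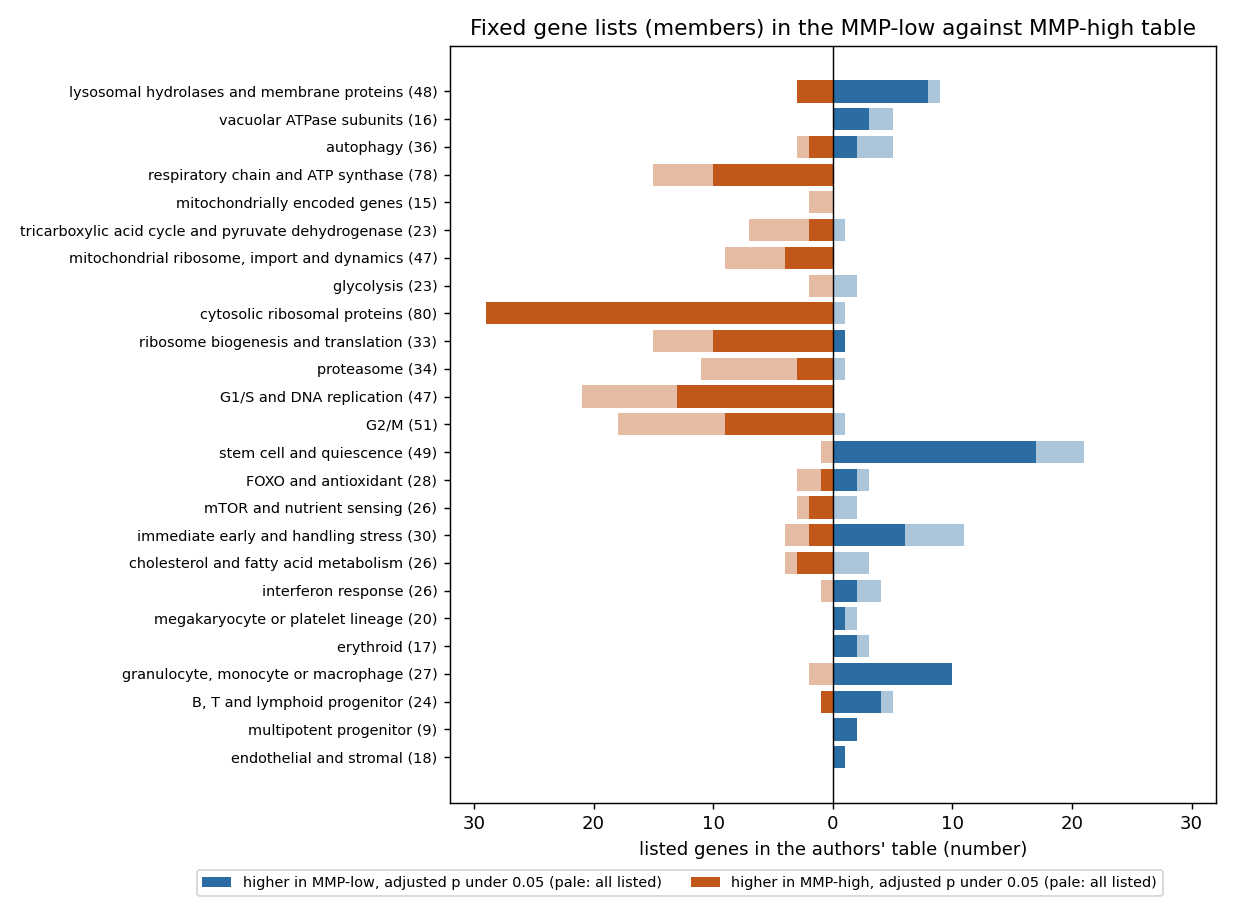
Number of genes of each fixed list that the authors' deposited table gives as higher in MMP-low (right, blue) or MMP-high (left, orange), with the number of list members in parentheses; dark parts have an adjusted p under 0.05. Stem cell genes lie mostly to the right, 21 against 1, and cytosolic ribosomal proteins to the left, 29 against 1.

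Some genes were detected in 1 group and not in the other. The authors' deposited table held 39 genes that were higher in MMP-low and detected in 0% of MMP-high cells, among them Ighm, Igkc, Cd79a, Igll1, Mmp8, Lgals3 and Fgr, of which Igkc, Mmp8, Lgals3 and Fgr, as well as Lrrn4, were chosen after their values were seen. These 39 genes were detected in 46.7% to 70.5% of MMP-low cells in the authors' deposited table, and the 53 genes detected in at most 1% of MMP-high cells reached 73.3%. In the other direction the authors' deposited table held 1 such gene, Lrrn4, detected in 67.2% of MMP-high and 0% of MMP-low cells, and 5 genes detected in at most 1% of MMP-low cells, which reached 69.7%. For comparison, libraries numbered up to 85 made up 69.7% of the MMP-low group (exact Clopper-Pearson 95% interval 60.7% to 77.7%) and 67.5% of the MMP-high group (58.5% to 75.5%). How many cells stand behind the authors' percentages is not stated, so no interval is given for them.

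Genes of the sex chromosomes were also listed, and these were chosen after their values were seen. Eif2s3y, Ddx3y and Uty lie on the Y chromosome and were detected in 89.5%, 70.5% and 65.7% of MMP-low cells against 12.6%, 8.4% and 5.0% of MMP-high cells in the authors' deposited table. Xist, the RNA that silences 1 X chromosome in female cells, was detected in 96.2% of MMP-low and 100% of MMP-high cells in the authors' deposited table. By these shares, at least 85.7% of MMP-low cells must have held both Eif2s3y and Xist. Of the X-linked genes in the authors' deposited table, 32 were higher in MMP-high and 30 in MMP-low. Xist was among the former, with a log fold change of 0.63 and an adjusted p of 0.11 in the authors' deposited table. So was Eif2s3x, at 0.46 with an adjusted p of 9.0e-07, detected in 94.1% of MMP-high and 64.8% of MMP-low cells. The sex of the donor animals is not given in the sources used here.

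**Figure D3:**
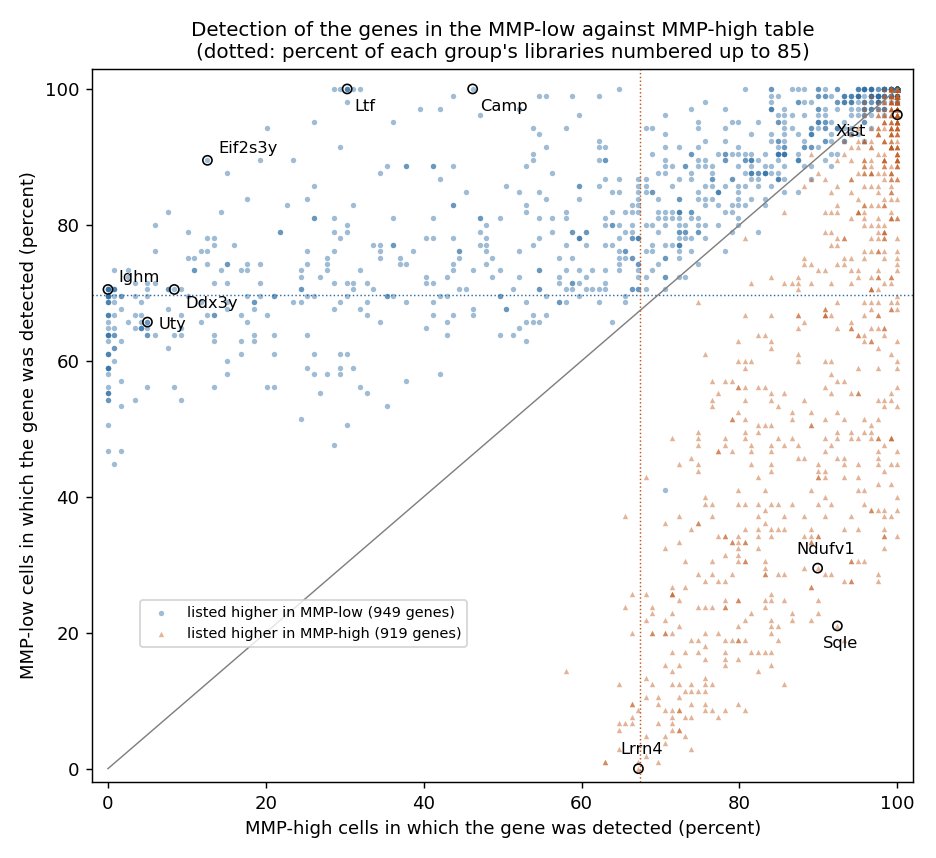
Percent of MMP-low cells (vertical axis) against percent of MMP-high cells (horizontal axis) in which each gene of the authors' deposited table was detected, with the diagonal in grey and dotted lines at the percent of libraries numbered up to 85 (69.7% and 67.5%). Genes detected in 0% of MMP-high cells reach at most 70.5% of MMP-low cells.

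The authors' term tables followed the same division. For genes higher in MMP-low, the biological process with the smallest adjusted p in the authors' deposited table was neutrophil degranulation, with 65 of its 487 genes (2.71e-10), and among cellular components it was the tertiary granule lumen, with 15 of 59 genes (4.55e-05). The lysosome held 19 of 168 genes in the authors' deposited table (2.17e-02). For genes higher in MMP-high, the authors' deposited table led among biological processes with rRNA processing, with 50 of 181 genes (2.31e-22), and translation, with 42 of 155 (1.99e-18), and DNA replication was the ninth, with 27 genes (3.01e-11). Its cellular components in the authors' deposited table included the mitochondrion, with 95 of 921 (7.58e-12), and its molecular functions had smaller values, such as double-stranded RNA binding, with 195 of 1223 (9.41e-54). Among transcription factor targets, the authors' deposited table led with TAF1 (349 genes, 1.36e-54) and MYC (218 genes, 1.08e-53) for MMP-high, and with SPI1, a regulator of myeloid and B cells, (98 genes, 1.21e-08) and RUNX1, a regulator of HSCs, (100 genes, 2.21e-05) for MMP-low. The background behind these adjusted p values is not stated.

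The authors divided the cells into 5 clusters, A to E, and the deposited gene tables set clusters A and B apart from D and E. Predicted genes were left out of the leading genes named for each cluster. Cluster A was led by Mgst1, Cpne8, Psap, Chil3 and Zfp975, with log fold changes from 1.35 to 0.77 against all other cells in the authors' deposited table, in a log base not stated. It held 16 stem cell genes, 12 immediate early genes, 10 lysosomal genes and 6 vacuolar ATPase subunits in the authors' deposited table, of which 9, 3, 7 and 5 had an adjusted p under 0.01, and Psap had an adjusted p of 0.72. Markers of other cells stood in it as well, 5 granulocyte and 3 erythroid genes in the authors' deposited table, all with an adjusted p under 0.01. Cluster B was led by S100a8 (2.09), S100a9 (2.08), Camp (1.96), Ltf (1.94) and Ngp (1.77) in the authors' deposited table, and held 7 granulocyte, 3 lymphoid and 10 lysosomal genes, of which 2, 3 and 3 had an adjusted p under 0.01, while S100a9 had 0.081. Ighm, chosen here after its values were seen, was detected in 100% of the cells of clusters A and B in the authors' deposited table, against 16.2% and 23.5% of the cells outside each.

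Cluster C was led by Tbc1d20, Ddx60, Trim34a, Nsun4 and Gaa, the lysosomal alpha-glucosidase, with log fold changes of at least 0.86 in the authors' deposited table. It held 11 genes of G1/S and DNA replication, such as Rrm2 (0.55), and 6 of the interferon response, such as Irf7 (0.65), in the authors' deposited table, of which 7 and 4 had an adjusted p under 0.01. Cluster D was led by Vav1, Gpn1, Ppp6c, Bcap29 and Usp1, and held 7 genes each of G1/S and of G2/M and 6 ribosomal proteins in the authors' deposited table, of which 2, 3 and 2 had an adjusted p under 0.01. Among these leaders of cluster D, Vav1 and Bcap29 had an adjusted p of 1, Usp1 of 0.25 and Ppp6c of 0.096 in the authors' deposited table. Cluster E was led by Faap100, Ptcd3, Mier2, Naa50 and Muc13, and held 5 genes of G1/S and 3 of the respiratory chain in the authors' deposited table, of which 0 and 0 had an adjusted p under 0.01. Neutrophil degranulation had the smallest adjusted p among biological processes for cluster A (50 genes, 6.22e-05) and cluster B (46 genes, 1.90e-06) in the authors' deposited tables, rRNA processing for cluster D (17 genes, 6.15e-03). The lysosomal membrane led the cellular components of cluster A with 40 of 347 genes (7.90e-06) in the authors' deposited table.

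Genes of clusters A and B overlapped with the MMP-low list and those of D and E with the MMP-high list. The authors' deposited tables shared 556 of 854 cluster A genes (65.1%) and 407 of 674 cluster B genes (60.4%) with the genes higher in MMP-low, and 0 of either with those higher in MMP-high. For cluster D, 279 of 524 genes (53.2%) were shared with the MMP-high list and 0 with the MMP-low list, and for cluster E 223 of 454 (49.1%) and 1, in the authors' deposited tables. Cluster C, with 830 genes, shared 7.23% with the MMP-low and 14.6% with the MMP-high list in the authors' deposited tables. Independent lists of these sizes among the 16203 genes tested would share 50.02, 39.5, 29.7 and 25.7 genes for A and B with MMP-low and D and E with MMP-high. For cluster C they would share 48.6 genes with MMP-low, near the number found, and 47.1 with MMP-high. The tables rest on the same cells and so share their chance values. Ighm was detected in 100% of the cells of clusters A and B and in 0% of MMP-high cells. By these shares clusters A and B held no MMP-high cells, so their overlap with the MMP-low list follows in part from which cells they hold. The numbers for independent lists are therefore no fair measure of that overlap. Among the 100 leading genes of each of the authors' deposited tables, the shares fell to 35% for cluster D and 18% for cluster E, and for cluster C they were 5% with MMP-low and 1% with MMP-high, so that its order turned. With an adjusted p under 0.01, the authors' deposited table kept 600, 217, 465, 270 and 142 genes for clusters A to E.

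**Figure D4:**
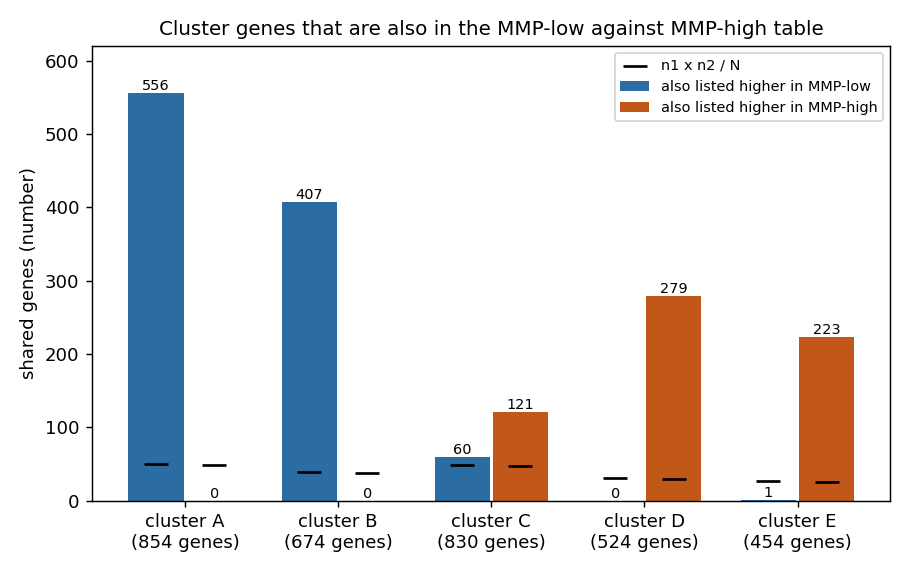
Number of genes of each authors' cluster that are also listed higher in MMP-low (blue) or MMP-high (orange), with black marks at the number for independent lists (n1 x n2 / N). Clusters A and B share 556 and 407 genes with the MMP-low list and 0 with the MMP-high list, and clusters D and E share 279 and 223 with the MMP-high list.

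Values of 13 pathways per cell were compared between the clusters by the authors, and only the z statistics of the pairs are in the deposited table. The direction of z is not stated. Read as column minus row, the authors' deposited table put cluster E first in 11 pathways, such as the electron transport chain, oxidative phosphorylation and glycolysis, cluster A first in the other 2, lysosome and lysosomal vesicle biogenesis, and cluster B last in all 13. The first cluster was starred against every other cluster in only 8 of the 13 pathways and the last in only 6, so the other first and last places are not set apart in the authors' deposited table. The opposite reading would reverse each order. For the lysosome, the pair of cluster D as column and A as row had a z of -8.65 and was starred, and the pair of A as column and E as row had a z of 1.41 and was not, in the authors' deposited table. Over all pathways 91 of 130 pairs were starred in the authors' deposited table.

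The authors also set the MMP groups beside genes of HSC classes labelled dHSC and aHSC, abbreviations that the files do not explain. Genes higher in MMP-low overlapped more with the dHSC list and genes higher in MMP-high with the aHSC list. At 1.5-fold, the authors' deposited table counted 66 dHSC genes in the MMP-low and 10 in the MMP-high list, against 19.8 and 19.5 for independent lists among 16203 genes. For aHSC genes the numbers in the authors' deposited table were 4 and 18, against 9.56 and 9.43. The number of genes that the authors' deposited table states for each MMP list, 465 and 459, could not be rebuilt at 1.5-fold from the comparison table, which gave 349 and 202 if the log is natural and fewer if it is log2. A list of 99 genes shared by MMP-low and dHSC in the authors' deposited table included the stem cell genes Ifitm1, Ly6a, Mllt3 and Procr beside the granulocyte genes Camp, Ngp, Lyz2 and Hp. A list of 55 genes shared by MMP-high and aHSC in the authors' deposited table included Stmn1, Ndufv1, Oxct1, Tyms and Cdk1. For 8 pathways, the authors' deposited table gave lower values in dHSC than in aHSC and lower values in MMP-low than in MMP-high.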

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

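The alternatives at an adjusted p under 0.05, at a natural log 2-fold, without nearly absent genes, without markers, at 300000 to 600000 mapped reads, in windows of exonic reads and by the share of list members were chosen after the data had been seen, and the others before the data were examined. Of 92 alternative values of the main results, 61 kept their direction and stayed within 1.5 times (counts), the SD over cells or counting interval. Part of these 61 could not have changed. No library met the stated gene minimum, so the share passing the filter could not rise where that minimum was kept or raised. Every library passed the read minimum, so a lower minimum or a subset of libraries could not alter that share. Listing each symbol once could not alter a count either. The 61 thus do not measure how stable the results are. No paired analysis was possible because the title numbers shared by the groups only name cells, and the gene tables hold no values per cell. For libraries numbered above 85 the median difference of MMP-high minus MMP-low turned to -178 genes detected and to -154498 total reads, from 1479 and 195297. Up to 85, it moved to 2746 genes at 100000 to 200000 exonic reads; explanations for the genes detected are weighed under other observations. The share passing the read minimum moved to 34.4% (MMP-low) and 48.4% (MMP-high) with mapped reads in place of total reads and to 90.2% of MMP-low libraries at 1000000 reads. In the authors' deposited table, the genes higher in MMP-low and MMP-high numbered 539 and 598 at an adjusted p under 0.05, 486 and 542 under 0.01, 428 and 455 under 0.001, 29 and 0 at 2-fold if the log is log2, and 72 and 9 if it is natural; these alternatives keep fewer genes by construction. The excess of 30 genes on the MMP-low side turned to -59, -56 and -27 under the adjusted p limits and to -18 without genes detected in at most 1% of the other group, and was 11 without markers and 63 at 2-fold in natural log. The number of lists outside the central 95% was 12 by median and 7 among genes with an adjusted p under 0.01, where fewer lists had 5 genes left and the ribosomal protein list, with 29 of its 30 genes, moved inside, from percentile 1.69 to 5.84. It was 14 by mean and 11 by share. By mean or share the respiratory chain and proteasome lists lay outside and the interferon list inside; by mean the lymphoid list lay outside, and by share the lysosomal and immediate early lists lay inside. At an adjusted p under 0.01, the authors' deposited table kept 217, 465, 270 and 142 genes for clusters B to E. The percent of cluster C genes higher in MMP-low moved to 0.860% under that limit, and among the 100 leading genes the percent higher in MMP-high was 1% for cluster C (5% in MMP-low, so that the order turned), 35% for D and 18% for E; the cause was not tested. Not run were the comparison within libraries passing the stated filter (0 pass), random lists not matched on mean expression as a separate setting (none were matched, as the table gives no mean) and all alternatives on values per cell (no such table). Listing each symbol once changed nothing, as no symbol was repeated. Depth could be matched only for part of the libraries numbered up to 85, as 26 MMP-low and 0 MMP-high libraries lay under 50000 exonic reads, and the number of cells behind the authors' percentages is not stated.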

Other observations

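The split of libraries at title number 85 was planned, and all the tests of explanations below were chosen only after the result they measure had been seen.

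Cluster C differed from the other cells in how often some genes were detected. Elane, neutrophil elastase, was detected in 82.4% of cluster C cells and 0% of other cells in the authors' deposited table, with a log fold change of 0.30 in a base not stated. Trim34a, of a family with interferon-induced members, was detected in 98.5% and 12.8%, Atg16l1, an autophagy factor, in 100% and 40.4%, and Rrm2, a subunit of ribonucleotide reductase, in 98.5% and 38.5% in the authors' deposited table. Of the predicted genes in the authors' deposited table, 55 were higher in MMP-low and 62 in MMP-high. Of the former, 8, chosen after their values were seen and led by Gm10800 on chromosome 2, had log fold changes from 1.03 to 1.88. These 8 are not all separate loci. Gm10722, Gm11168, Gm10719 and Gm10717 lie within the span of Gm26870 on chromosome 9 (3000282 to 3038313). Gm10801 (98662237 to 98664083) lies near Gm10800 (98666547 to 98667301) on chromosome 2. Gm21738 lies apart from these, on chromosome 14 (19415857 to 19418930). The authors' deposited term list headed MMP-high and aHSC held 14 of 39 terms that name leukocytes, neutrophils, granulocytes or myeloid cells, and the list headed MMP-low and dHSC held 0 of 7, with 2 that name mRNA or ribonucleoproteins. The granulocyte genes stood in the MMP-low and dHSC gene list, so whether the term headings are in the right order is in doubt.

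Transcripts of granulocytes and B cells were listed higher in MMP-low cells, which were sorted as lineage-negative. For the share of cells that detect these genes, a minority of cells of another type in the MMP-low sort is argued against by the authors' deposited table, since the 10 granulocyte genes had a median detection of 100% of MMP-low and 39.1% of MMP-high cells, unless detection was filled in by the authors' processing. For the size of the folds such a minority cannot be told apart from a difference in all cells, as 7 of these genes had a median log fold change of 1.94 in cluster B and 5 had 0.58 in cluster A, 30.04% of the former, in the authors' deposited table, and no values per cell are given. RNA from other marrow cells in the MMP-low wells may add such transcripts to every well; 3 lineage marker lists leaned to MMP-low, but granulocyte and lymphoid lists are the pattern itself, so this and a true difference between the groups cannot be told apart with only the erythroid list left, where the authors' deposited table gave Hbb-bt in 71.4% of MMP-low and 58.8% of MMP-high cells. Many listed genes were detected in every cell of their group, 150 of 949 for MMP-low and 284 of 919 for MMP-high. Among cluster genes, those detected in every cell of the cluster ranged from 222 of 830 for C to 383 of 454 for E. Without values per cell these counts cannot decide whether detection was filled in. Genes detected in 0% of MMP-high cells, such as Ighm, reached at most 70.5% of MMP-low cells, while libraries numbered up to 85 made up 69.7% of that group. The granulocyte genes, at a median of 100% of MMP-low cells, were not bounded in this way. A difference between library batches, values filled in by the authors' processing, and a biological difference by membrane potential stay open as untested.

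Y-linked transcripts were listed higher in MMP-low cells. Male donors for MMP-low cells and female donors for MMP-high cells, with no other difference, are argued against by the smallest share of MMP-low cells that held both Xist and Eif2s3y, 85.7% from the authors' deposited table. RNA of both sexes in the MMP-low wells, from mixed donors or wells, needs such a share, but this is the same value, seen beforehand, and gives no separate support. Detection filled in by the authors' processing was not tested and may give the same share. No biological explanation was tested, as the labels give no sex.

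The group difference in genes detected was carried by the libraries numbered up to 85. Sequencing depth is argued against, since at 300000 to 600000 mapped reads and numbers up to 85 the medians still differed by 2043 genes, and in the 5 windows of exonic reads that held both groups by 774 (with 1 MMP-high library) to 2746, while the lowest window held 26 MMP-low and 0 MMP-high libraries. A difference between library batches cannot be told apart from one by group, since the -178 genes above 85, against 1580 up to 85, are the pattern itself and lane and group can be confounded up to 85. RNA quality as measured by the expression profiling efficiency was 12.1% in MMP-low and 24% in MMP-high at these mapped reads. It is argued against as the whole cause only in the windows of exonic reads where it was matched. At 500000 to 1000000 exonic reads it was 63.3% in MMP-low and 61.7% in MMP-high, and at 1000000 to 2000000 it was 65.8% and 65.7%. There the medians still differed by 1270 and 1128.5 genes, with SDs over cells of at most 525. These windows held 13 and 11 of 85 MMP-low libraries and 36 and 18 of 85 MMP-high libraries, and the others were not matched in efficiency. The alignment rate also differed up to 85, with medians of 53.6% in MMP-high and 31.2% in MMP-low. At 500000 to 1000000 exonic reads it was still unmatched, at 58.5% in MMP-high and 41.8% in MMP-low. At 1000000 to 2000000 it was 63.2% in MMP-high and 61.2% in MMP-low. Other sides of RNA quality, the alignment rate among them, and a difference by membrane potential that shows only in some libraries, stay open as untested.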
